A study of Mus musculus with 20 samples.

How the data were processed

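The series holds mouse cells (strain label 159.2) at 3 stages of neuronal differentiation, namely progenitors and neurons at day 1 and at day 10, and day 10 neurons given 200 µM NMDA or DMSO alone for 6 h, per the labels. NMDA is an agonist of the NMDA class of glutamate receptors. FAIRE-seq, which sequences DNA freed of nucleosomes, was done at the 3 stages. ChIP-seq for H3K27ac, a histone mark of active promoters and enhancers, was done at the 3 stages and in the NMDA and control cultures, and RNA-seq in the NMDA and control cultures. Each group had 2 libraries. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

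Per the submitters' processing notes, the genome build was mm9 and the tools were TopHat, Bowtie, HTSeq and DESeq; their versions, roles and parameters, the peak caller, the annotation and the strandedness of the RNA libraries are not given in the sources used here. Where a gene overlaps another or an antisense partner, the reads of the pair cannot be told apart.

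The RNA table held, for 21937 gene symbols, a signal that the authors deposited as normalised read counts, 1 column per library. The deposited values were whole multiples of 1 step per library, between 0.878 and 1.20 per read, so whole reads could be recovered. Of the values, 99.95% to 99.995% came out whole within a tolerance of 0.0051. The recovered depth was 20.1 M and 15.0 M reads for the control libraries and 20.1 M and 16.8 M for the NMDA libraries, where M stands for 1e+06. Of the symbols, 19767 matched a current mouse symbol, 1974 an older one and 196 neither; the names came from tables of the GRCm38.p6 assembly, which was used for names only.

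The 3 chromatin tables held log2 values that the authors deposited as merged enrichment, 1 value per region and group with both libraries merged, together with a region identifier and a width in bp. Columns with values per library, region coordinates and a link from regions to genes were not used here. The base of the logarithm was settled from the values: 2 raised to the difference of 2 columns was a ratio of small whole numbers in 99.75% to 100% of the 400 rows examined per table, against 2% to 5.5% for base e or 10. Each value was the log2 of the merged reads plus 16 over a scaled reference plus 16, with 1 reference for all columns of a table. Reads could be recovered for 99.97% to 99.99% of regions. Whether the merged libraries had been matched in depth is not given in the sources used here, and what the reference was is not either. The tables were made separately, so values were compared only within a table.

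Genes with a mean of at least 10 normalised counts over the 4 libraries were tested with limma-trend (limma 3.58.1, R 4.3.3) on log2(value + 1), with the group as the only term, 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on that scale, which understates the change of low genes. edgeR's quasi-likelihood test (edgeR 4.0.16) and DESeq2 (1.42.0) on the recovered reads were alternatives. Gene lists, 35 in all, and the rule for named genes were set before the data were examined. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. With 2 libraries per group the test with an estimated correlation has few degrees of freedom and could hardly call any list. A call lost with it therefore does not tell whether correlation among the genes had made that call. The lists cover immediate early and late activity-response genes, the unfolded protein, heat shock and oxidative stress responses, p53 targets, apoptosis, NF-kappaB, neurotrophins, glutamate and GABA receptors, synapse and channel genes, neuronal and other cell type markers, the cell cycle, pluripotency, cholesterol synthesis, glycolysis, the respiratory chain, histones, chromatin enzymes and RNA quality. Members were matched by symbol, and those without a match were not analysed here.

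Named genes were the 12 largest rises and 12 largest falls among genes past the threshold with a mean of at least 50 and no overlap between groups, with predicted and unnamed gene models left out, and up to 4 members per list with the smallest p past the threshold, or the 2 with the highest mean where none passed. Not all of them are printed. A few other genes are named with the remark that they were chosen after their values were seen. For the chromatin tables, tests between groups of libraries had been planned; with merged values there is no spread between replicates, so no test was run there. The size of a change is given in their place, with counts of regions that differed by at least 2-fold (a log2 difference of 1 or more). Beside them stands the count that binomial sampling of the recovered reads would give, with a common factor for the difference in total reads between groups. Comparing FAIRE with H3K27ac at shared regions, the NMDA with the developmental change at shared regions, and H3K27ac near genes changed in RNA had been planned too, and could not be done without coordinates.

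The 2 control libraries differed by more than sampling noise, with a chi-square per degree of freedom of 4.49 over genes, and the NMDA libraries likewise with 15.0, so none was a second copy of another. Their log2 values correlated at 0.994 and 0.990 across genes. The steps were tested on simulated data. With 2 libraries per group and 13905 genes, limma recovered 100% of 100 genes changed by 2-fold and 74% of 100 changed by 1.5-fold, with 4 unchanged genes called. The recovery of reads returned the exact reads in 100% of 5000 simulated regions. In 20000 simulated regions with a mean of 40 reads, the 2-fold limit found 100% of regions raised 6-fold, 90% of those lowered 6-fold, and it called 0 of the unchanged regions. The simulated groups were equal in depth. The chromatin tables had medians of 10 to 27 reads per region and unequal reads between groups, so these rates do not carry over to them. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the chromatin tables and the plots. Exact binomial intervals at 95% cover counting error only. The alternatives tried were other pseudocounts (5 and 0.5), other filters, quantile normalisation, other tests, a replicate block, leaving out each library, other thresholds, and, for the chromatin tables, quantile normalisation, median-centring, a filter on low values and a constant of 4 reads.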

Results

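The data describe mouse neurons made in culture, measured as they matured and after stimulation. FAIRE-seq gave an enrichment value for 62877 regions in progenitors of neurons and in neurons at day 1 and at day 10, and ChIP-seq for H3K27ac gave one for 140641 regions at the same stages. In day 10 neurons given NMDA (200 µM for 6 h) or DMSO as the control, H3K27ac was measured over 119345 regions and RNA over 21937 genes. All 10 groups had 2 libraries. The RNA libraries held 20.1 M and 15.0 M reads in the control group and 20.1 M and 16.8 M after NMDA. The chromatin values were the authors' merged values, so they carry no replicate error. Reads in regions came to 2.38 M, 1.87 M and 1.03 M for FAIRE in progenitors and at day 1 and day 10, and to 18.0 M, 15.3 M and 11.2 M for H3K27ac. In the NMDA experiment they were 12.9 M for the control and 9.34 M for NMDA.

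The RNA comparison asked which transcripts differed between day 10 neurons after 6 h of NMDA and their controls. The largest rise was that of Npas4, an activity-dependent transcription factor, from 48.9 ± 7.00 to 448 ± 63.1 normalised counts (SD, n = 2 each), a log2 change of 3.17 ± 0.17 (SE; limma adjusted p = 0.000565). Genes of the AP-1 factors followed, with Fosb up by 2.68 ± 0.22 and Fos by 2.19 ± 0.21 on the log2 scale. Ptgs2, the inducible cyclooxygenase, rose by 2.40 ± 0.46, although its NMDA libraries lay far apart (99.1 ± 70.6 against 15.4 ± 0.219 in the controls). Cyr61 and Ctgf, which encode matricellular proteins, rose by 2.17 ± 0.31 and 2.15 ± 0.16. Nr4a1, a nuclear receptor, rose by 1.76 ± 0.20, Csrnp1 by 1.71 ± 0.22 and Lcat by 1.71 ± 0.33. Hspa1a and Hspa1b, inducible Hsp70 genes, rose by 1.88 ± 0.12 and 1.73 ± 0.14; their sequences are nearly identical and share reads, so the split between them is uncertain. The largest fall was that of Otop1, a proton channel gene, from 91.9 ± 5.53 to 16.6 ± 1.29 counts (log2 change -2.40 ± 0.24, limma adjusted p = 0.000703). Col10a1, a collagen gene, fell by 2.11 ± 0.24 and the zinc finger genes Zfp39, Zfp941 and Zfp128 by 2.01 ± 0.28, 1.95 ± 0.16 and 1.64 ± 0.26. Cntnap5c fell by 1.81 ± 0.24, Neu3, a sialidase gene, by 1.61 ± 0.16, Syt2, a synaptic calcium sensor, by 1.59 ± 0.13 and Pcdh15, a protocadherin, by 1.51 ± 0.13. The smallest adjusted p among the genes named here was 0.000565 and the largest of the rises was 0.00489. Of 13888 genes tested, 2845 rose and 2979 fell at an adjusted p under 0.05. Of these, 495 rose and 209 fell by at least 2-fold. The groups did not overlap in 74.5% of all tested genes, against 33.3% expected by chance for 2 libraries against 2. Without control replicate 1 there were 1060 rises and 910 falls, and without control replicate 2 there were 1406 and 1338.

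**Figure D1:**
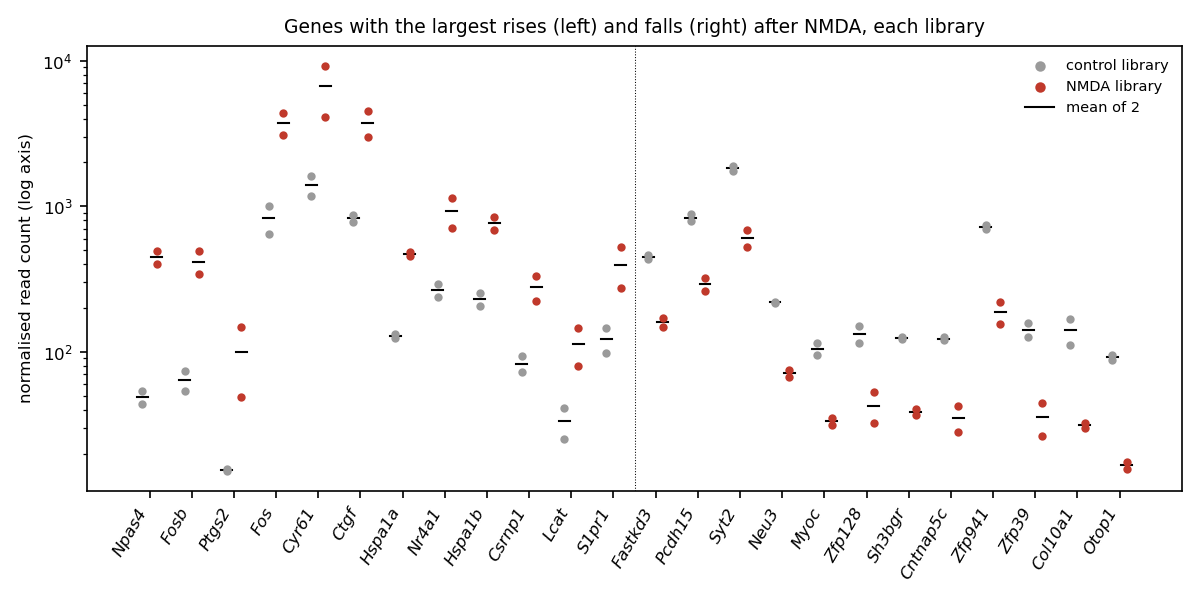
Normalised read counts (log axis) of the 24 genes with the largest rises and falls after NMDA; grey points are the 2 control libraries, red points the 2 NMDA libraries, and bars their means. Npas4 rose from 48.9 to 448 and Otop1 fell from 91.9 to 16.6.

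Most immediate early genes, which neurons switch on within minutes to hours of activity, rose. Of 28 tested, 24 rose and 1 fell, Jun, with a log2 change of -0.41 ± 0.13 (limma adjusted p = 0.0373; singled out after its value was seen). Its call was lost without control replicate 1 (adjusted p = 0.0814), control replicate 2 (0.292) or NMDA replicate 1 (0.127) and with quantile normalisation (0.0796). Adjusted over the list alone, 26 rose and 1 fell. The median log2 change was 1.24 (camera adjusted p = 9.26e-08, but adjusted p = 0.602 with an estimated correlation), and 0.72 without NMDA replicate 2. Btg2, an antiproliferative gene also among the p53 targets, rose by 1.46 ± 0.15. Of 29 late activity-response genes, 13 rose and 2 fell, and the same numbers held adjusted over the list alone (median 0.33, camera adjusted p = 0.0196, but adjusted p = 0.602 with an estimated correlation). Vgf, a neuropeptide precursor, rose by 1.09 ± 0.18, Plat, tissue plasminogen activator, by 1.01 ± 0.12 and the neurotrophin gene Bdnf by 0.91 ± 0.17, while Nfil3, a transcriptional repressor, fell by 0.88 ± 0.11. The first list had 13 rises without control replicate 1, and the late list 7 rises and 1 fall. In the same libraries, the fibroblast and mesenchyme markers had a median log2 change of 1.06 and the pan-neuronal markers of -0.25 (-0.16 without NMDA replicate 2).

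Among the 5 lists of stress and death genes, the p53 targets had the largest median change. Of 20, 14 rose and 1 fell (15 and 1 adjusted over the list alone), with a median log2 change of 0.66 (camera adjusted p = 0.00044, but adjusted p = 0.602 with an estimated correlation); Pmaip1, a proapoptotic BH3 gene, rose by 0.96 ± 0.11. Of 24 apoptosis genes 8 rose and 1 fell (the same adjusted over the list alone, median 0.26, camera adjusted p = 0.039, but adjusted p = 0.602 with an estimated correlation), with Bax up by 0.55 ± 0.08. Of 17 oxidative stress genes 7 rose and 10 did not pass (8 rose adjusted over the list alone; median 0.28, camera adjusted p = 0.0196, but adjusted p = 0.602 with an estimated correlation), with Hmox1, heme oxygenase 1, up by 0.92 ± 0.17. The unfolded protein and integrated stress list was mixed, with 8 of 24 up and 5 down (9 and 6 adjusted over the list alone; median 0.21, camera adjusted p = 0.372): Atf5 rose by 0.76 ± 0.12 and Herpud1, an ER-associated degradation gene, fell by 0.85 ± 0.10. Of 19 heat shock genes, 7 rose and 3 fell, as they did adjusted over the list alone (median 0.17, camera adjusted p = 0.0993). Leaving out control replicate 1, apoptosis genes had 2 rises, oxidative stress genes 2, the unfolded protein list 4 rises and 4 falls and heat shock genes 5 rises and 1 fall, and without control replicate 2 the apoptosis and unfolded protein lists had 4 and 3 rises. Without NMDA replicate 2 the unfolded protein list had 5 rises, and the medians were 0.16 for apoptosis genes, 0.18 for oxidative stress genes and 0.11 for the unfolded protein list, which stood at 0.08 among genes with a mean of at least 50. In the same libraries the median log2 change was 1.06 for fibroblast markers, 0.87 for progenitor markers and -0.25 for pan-neuronal markers (-0.16 without NMDA replicate 2).

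Of the genes of neuronal receptors, synapses and channels, some fell and few rose. Every call of these lists by camera was lost with an estimated correlation, a test that could hardly call any list with 2 libraries per group. Among NMDA receptor subunits 4 of 6 fell and 2 did not pass (median log2 change -0.56, camera adjusted p = 0.0323, but adjusted p = 0.602 with an estimated correlation): Grin3a by 0.93 ± 0.10, Grin2b by 0.67 ± 0.11 and Grin1, the obligatory subunit, by 0.56 ± 0.13, the last losing its call without control replicate 1 (adjusted p = 0.111) or control replicate 2 (adjusted p = 0.0673). Of 7 metabotropic glutamate receptors 5 fell (median -0.44, camera adjusted p = 0.0209, but adjusted p = 0.602 with an estimated correlation), among them Grm7 by 0.92 ± 0.11. Of 26 synaptic vesicle and presynaptic genes 13 fell (16 adjusted over the list alone; median -0.35, camera adjusted p = 4.84e-05, but adjusted p = 0.602 with an estimated correlation), with the active zone genes Rims2 and Pclo down by 0.98 ± 0.10 and 0.89 ± 0.10. Of 23 potassium channel genes 10 fell (median -0.52, camera adjusted p = 0.00063, but adjusted p = 0.602 with an estimated correlation), with Kcnma1 down by 0.96 ± 0.13, and of 23 calcium and sodium channel genes 11 fell (12 adjusted over the list alone; median -0.37, camera adjusted p = 0.00537, but adjusted p = 0.602 with an estimated correlation), with the sodium channel Scn8a down by 0.96 ± 0.10. Of 24 postsynaptic density genes 10 fell and 1 rose (median -0.20, camera adjusted p = 0.0191, but adjusted p = 0.602 with an estimated correlation), with the synaptic adhesion gene Nlgn1 down by 0.86 ± 0.12. Pan-neuronal markers were 9 down and 1 up of 21 (10 and 1 adjusted over the list alone; median -0.25, camera adjusted p = 0.0421, but adjusted p = 0.653 with an estimated correlation); the neurofilament gene Nefm fell by 0.81 ± 0.11 and Rbfox3, which encodes NeuN, by 0.48 ± 0.08, its call lost without control replicate 2 (adjusted p = 0.0508). AMPA and kainate receptors had 6 falls among 14 (median -0.25, camera adjusted p = 0.0519). This list passed camera with the replicate block (adjusted p = 0.0298), but not with an estimated correlation and no block (adjusted p = 0.602). GABA receptors had 3 falls among 13 (median -0.27, camera adjusted p = 0.155), with Gabbr2 down by 0.60 ± 0.11. Where no separate count is given, the counts adjusted over the list alone were the same. Markers of glutamatergic neurons gave 1 rise and 2 falls of 11 (median -0.16, camera adjusted p = 0.717) and those of GABAergic neurons 1 rise and 1 fall of 12 (median 0.01, camera adjusted p = 0.738; this median was -0.06 without control replicate 2, -0.17 without NMDA replicate 1, 0.11 without NMDA replicate 2, 0.05 without control replicate 1, 0.31 with no filter on low values and -0.09 among genes with a mean of at least 50), and in both the counts adjusted over the list alone were those numbers. These rises and falls were 0 and 1 (2 and 2 at an unadjusted p under 0.05) for glutamatergic markers and 1 and 0 (2 and 1 unadjusted) for GABAergic markers without control replicate 1 by limma. They were 1 and 1, and 1 and 0 (1 and 1 unadjusted), without control replicate 2, 2 and 3, and 1 and 4, without NMDA replicate 1, and 2 and 2, and 3 and 1, without NMDA replicate 2. For the other neuronal lists, falls without control replicate 1 were 2 for NMDA receptors, 2 for metabotropic receptors, 6 for presynaptic genes, 5 for potassium channels, 5 for calcium and sodium channels, 6 for the postsynaptic density, 4 for pan-neuronal markers, 1 for GABA receptors and 0 for AMPA and kainate receptors by limma (4 at an unadjusted p under 0.05). Without control replicate 2 the falls numbered 7 for presynaptic genes, 2 for pan-neuronal markers and 2, 3, 1 and 1 for the NMDA, metabotropic, AMPA and kainate, and GABA receptors. Without NMDA replicate 1 presynaptic genes had 24 falls and GABA receptors 7, and without NMDA replicate 2 metabotropic receptors had 3. Leaving out NMDA replicate 2 brought the medians to -0.34 for NMDA receptors, -0.09 for AMPA and kainate receptors, -0.12 for GABA receptors, -0.23 for presynaptic genes, -0.32 for potassium channels, -0.16 for pan-neuronal markers and -0.06 for glutamatergic markers. The median was -0.39 for AMPA and kainate receptors without NMDA replicate 1 and, without control replicate 1, -0.16 for GABA receptors. Among genes with a mean of at least 50 it was -0.68 for metabotropic receptors and -0.05 for glutamatergic markers, which had -0.07 with quantile normalisation. Fibroblast markers had a median of 1.06 and progenitor markers of 0.87 in the same libraries.

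**Figure D2:**
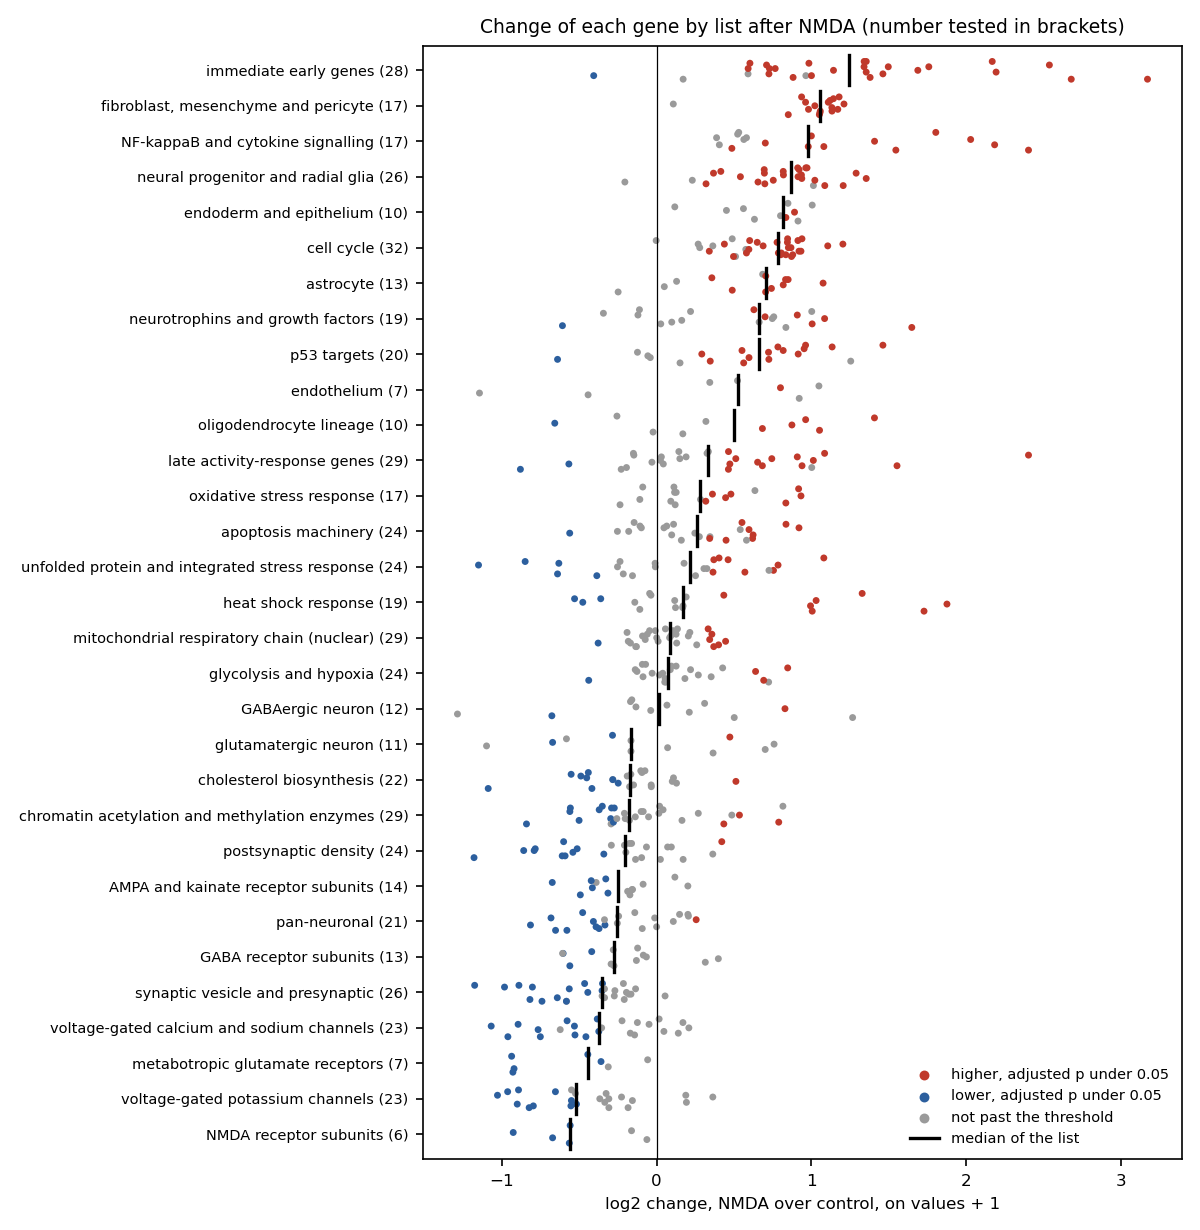
Each point is a gene of a list set before the data were examined, at its log2 change after NMDA (x axis, on values plus 1); black bars are list medians and colours mark genes past an adjusted p of 0.05. Among lists with at least 5 tested members, medians run from 1.24 for immediate early genes to -0.56 for NMDA receptor subunits.

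Most genes in the progenitor, cell cycle, fibroblast and astrocyte lists rose in the same libraries, while few endothelial and endoderm genes passed the test. Of 26 neural progenitor and radial glia genes, 23 rose and 3 did not pass, also adjusted over the list alone (median log2 change 0.87, camera adjusted p = 9.26e-08, but adjusted p = 0.602 with an estimated correlation), among them the Notch ligand Dll1 by 1.29 ± 0.13, Notch1 by 0.91 ± 0.09 and Nes, which encodes nestin, by 0.75 ± 0.10. Of 32 cell cycle genes 25 rose (28 adjusted over the list alone; median 0.78, camera adjusted p = 9.26e-08, but adjusted p = 0.602 with an estimated correlation), with Aurkb up by 1.20 ± 0.15 and Top2a by 0.88 ± 0.15. Of 17 fibroblast, mesenchyme and pericyte genes 16 rose (16 adjusted over the list alone; median 1.06, camera adjusted p = 5.00e-07, but adjusted p = 0.602 with an estimated correlation). They included abundant transcripts: Fn1, fibronectin, went from 12176 ± 1720 to 26339 ± 579 counts and Col6a1 from 4859 ± 704 to 10693 ± 993. Of 13 astrocyte genes 9 rose (9 up and 1 down adjusted over the list alone; median 0.70, camera adjusted p = 0.0132, but adjusted p = 0.602 with an estimated correlation), with the connexin gene Gja1 up by 1.08 ± 0.17. Oligodendrocyte lineage genes gave 5 rises and 1 fall of 10, as they did adjusted over the list alone (median 0.50, camera adjusted p = 0.104), and Olig1 rose by 1.05 ± 0.13. Endothelial genes gave 1 rise of 7, also adjusted over the list alone (median 0.52, camera adjusted p = 0.667). Endoderm and epithelium genes gave 2 of 10, none of them adjusted over the list alone (median 0.82, camera adjusted p = 0.0655). The endoderm list passed camera with the replicate block (adjusted p = 0.0018), but not with an estimated correlation and no block (adjusted p = 0.676). Only 2 microglia genes were tested, of which 1 rose, also adjusted over the list alone. The rises without control replicate 1 were 8 for progenitor genes, 12 for the cell cycle, 2 for astrocytes and 2 for the oligodendrocyte lineage. By limma they were 0 for endoderm and 0 for microglia, with 0 and 1 at an unadjusted p under 0.05. Progenitor genes had 15 rises without control replicate 2, and microglia genes 2 without NMDA replicate 1. For the oligodendrocyte lineage they were 3 without control replicate 2 or NMDA replicate 2. For endothelium there were 3 rises and 1 fall without NMDA replicate 1, and endoderm genes had 8 rises without NMDA replicate 1, 1 without control replicate 2 and, by limma, 0 without NMDA replicate 2 (0 at an unadjusted p under 0.05). Medians moved as well. The endothelial median turned to -0.0029 without control replicate 1 and to -0.11 without NMDA replicate 2, and was 0.85 without control replicate 2 and 1.23 without NMDA replicate 1. For endoderm genes it was 0.27 without control replicate 1, 0.35 without NMDA replicate 2 and 1.28 without NMDA replicate 1. The astrocyte median was 0.34 without NMDA replicate 2 and the oligodendrocyte median 0.93 without NMDA replicate 1. On all libraries edgeR gave 2 rises for endoderm genes and DESeq2 0.

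Of 17 NF-kappaB and cytokine genes 11 rose (12 adjusted over the list alone; median log2 change 0.98, camera adjusted p = 0.00063, but adjusted p = 0.602 with an estimated correlation). Of 19 neurotrophin and growth factor genes 6 rose and 1 fell, also adjusted over the list alone (median 0.66, camera adjusted p = 0.0347, but adjusted p = 0.602 with an estimated correlation). Cholesterol synthesis genes fell in 8 of 22 cases and rose in 1, with the same numbers adjusted over the list alone (median -0.17, camera adjusted p = 0.0383, but adjusted p = 0.653 with an estimated correlation); Lss, lanosterol synthase, fell by 1.09 ± 0.11. Chromatin acetylation and methylation enzymes gave 3 rises and 10 falls of 29 (4 and 10 adjusted over the list alone; median -0.17, camera adjusted p = 0.138), with Crebbp, the acetyltransferase CBP, down by 0.84 ± 0.08 and the deacetylase gene Hdac1 up by 0.79 ± 0.10. Glycolysis and hypoxia genes gave 3 rises and 1 fall of 24 (1 and 1 adjusted over the list alone; median 0.07, camera adjusted p = 0.204), and nuclear genes of the respiratory chain 6 rises and 1 fall of 29, also adjusted over the list alone (median 0.08, camera adjusted p = 0.271). All 4 core histone genes that could be tested rose, also adjusted over the list alone; paralogs of this family can share reads. Of 3 pluripotency genes 1 rose and 1 fell, also adjusted over the list alone, the fall being Esrrb, from 487 ± 68.4 to 198 ± 35.3 counts. Of 3 nuclear-retained transcripts in the RNA quality list 0 passed by limma, over all genes or adjusted over the list alone, with 1 higher and 1 lower at an unadjusted p under 0.05; edgeR called 1 lower, and DESeq2 called 1 higher and 1 lower. Malat1 had 8517 ± 67.9 counts in controls and 8406 ± 125 after NMDA (log2 change -0.02 ± 0.08). With control replicate 1 left out, rises were 2 for NF-kappaB genes, 3 for growth factors, 0 for the respiratory chain by limma (2 at an unadjusted p under 0.05) and 1 each for glycolysis and histones, and falls were 1 for cholesterol genes and 2 for chromatin enzymes. Without control replicate 2 there were 6 rises for NF-kappaB, 2 for the respiratory chain, 1 for glycolysis and 2 for histones, and 2 falls for cholesterol genes and 4 for chromatin enzymes. Without NMDA replicate 2 there were 6 rises for NF-kappaB, 1 for glycolysis, 2 for histones and 2 for cholesterol genes, with 5 falls for the last. Without NMDA replicate 1 there were 5 rises and 2 falls for glycolysis and 3 falls for the respiratory chain, and the pluripotency rise was lost without either control replicate. The median of the NF-kappaB list was 0.47 without NMDA replicate 2, and that of growth factors 0.39 without control replicate 1 and 0.16 among genes with a mean of at least 50. For glycolysis it was 0.12 without control replicate 2 and 0.11 with quantile normalisation, for the respiratory chain 0.0024 without NMDA replicate 1 and 0.18 with quantile normalisation, and for chromatin enzymes -0.12 with quantile normalisation. Fibroblast markers had a median of 1.06 and pan-neuronal markers of -0.25 in these libraries (-0.16 without NMDA replicate 2).

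The H3K27ac comparison after NMDA asked where acetylation differed from the control neurons. On the deposited scale the mark was lower over most regions: the merged log2 enrichment had a median of 0.91 in the control and 0.74 after NMDA, and 66.9% of the 119345 regions were lower. The median change was -0.21, with quartiles of -0.51 and 0.08. By at least 2-fold, 4391 regions were lower and 166 higher. Counting error with a common factor for the difference in reads would give 141 lower and 0 higher. Median-centred, 1632 were lower and 583 higher, so the share of higher regions among those changed went from 3.64% to 26.3%. With quantile normalisation 852 were lower and 671 higher, a share of 44.1%. Regions at least 2-fold over the reference numbered 54212 (45.4%) in the control and 42712 (35.8%) after NMDA. Across regions the groups correlated at r = 0.92 (Spearman 0.77), with regions not independent replicates and 1 reference shared by both groups. The largest rises among regions whose mean was at or above the median were DMSONMDA_H3K27Ac_peak_98426 (291 bp, 29 reads in the control and 114 after NMDA, a ratio of 3.93 with an exact 95% interval of 2.60 to 6.13) and DMSONMDA_H3K27Ac_peak_13764 (178 bp, 30 and 115 reads, ratio 3.83, interval 2.55 to 5.94). The largest falls were at DMSONMDA_H3K27Ac_peak_3140 (984 bp, 170 reads in the control and 28 after NMDA, ratio 0.165, interval 0.106 to 0.247) and DMSONMDA_H3K27Ac_peak_79902 (1449 bp, 583 and 132 reads, ratio 0.226, interval 0.186 to 0.274). The files do not pair regions with genes. With 1 merged value per group, whether these changes exceed the spread between libraries could not be tested.

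FAIRE signal, which marks open chromatin, fell step by step from progenitors to day 10 neurons on the deposited scale. The median log2 enrichment was 0.99 in progenitors, 0.79 in day 1 neurons and 0.44 in day 10 neurons, and regions at least 2-fold over the reference numbered 30916 (49.2%), 22376 (35.6%) and 8249 (13.1%). From progenitors to day 1, 28 regions rose and 639 fell by at least 2-fold, with a median change of -0.22. From day 1 to day 10, 32 rose and 5484 fell, with a median change of -0.40, and from progenitors to day 10, 26 rose and 14055 fell, with a median change of -0.61. Counting error with a common factor for the difference in reads would give 36, 1137 and 7589 falls and 0 rises in each. Median-centred, the rises and falls were 156 and 127, 292 and 995, and 734 and 2033. The share of rises among changed regions thereby went from 4.20% to 55.1%, from 0.58% to 22.7% and from 0.185% to 26.5%. With quantile normalisation the rises and falls were 58 and 39, 770 and 579, and 1058 and 916. The log2 ratio of day 10 over progenitor reads was -1.07 (bootstrap 95% interval -1.08 to -1.05) in regions with a mean enrichment of 1- to 2-fold, -1.32 (-1.37 to -1.27) at 2- to 4-fold and -1.25 (-1.35 to -1.14) at 4-fold or more, the last 2 intervals overlapping. In the 40 regions under 1-fold it was 0.07 (-0.33 to 0.40). These are merged values with no replicate check.

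H3K27ac moved in both directions across the stages. The median log2 enrichment was 0.66 in progenitors, 0.67 in day 1 neurons and 0.63 in day 10 neurons, and the share of regions at least 2-fold over the reference stayed at 34.0%, 34.6% and 34.0%. From progenitors to day 1 neurons, 9608 regions gained and 7801 lost at least 2-fold; from day 1 to day 10, 12529 gained and 18729 lost. From progenitors to day 10, 13898 gained and 21304 lost, against 0 and 1054 from counting error with a common factor for the difference in reads. Quantile normalisation turned the last 2 splits, to 14797 gains and 14397 losses from day 1 to day 10 and to 15952 and 15243 from progenitors to day 10. The log2 ratio of day 10 over progenitor reads was -0.99 (upper end of the bootstrap 95% interval -0.97) in regions with a mean enrichment of 4-fold or more, -0.07 (interval -0.09 to -0.04) at 2- to 4-fold, 0.07 (0.06 to 0.08) at 1- to 2-fold and -0.20 (-0.25 to -0.14) under 1-fold. Gain by day 1 followed by loss by day 10 was seen in 5293 regions, gain only by day 1 in 4058 and gain only between day 1 and day 10 in 11747; 257 gained at both steps. Loss at the first step alone was seen in 6236 regions, at the second alone in 12396 and at both in 1040, and 525 lost and then regained the mark. The numbers expected from independent steps were 1279 for gain then loss and 695 for loss then gain. Gain then loss was thus above its expected number and loss then gain below it. Sampling error of the reads gave 0 of each in simulation. Part of the excess of gain then loss may come from the day 1 libraries, which both steps share. Enrichment in progenitors and day 10 neurons correlated at r = 0.69 (Spearman 0.42) across regions for H3K27ac and r = 0.70 (Spearman 0.52) for FAIRE. The columns of a table share 1 reference, which can add to such correlations.

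**Figure D3:**
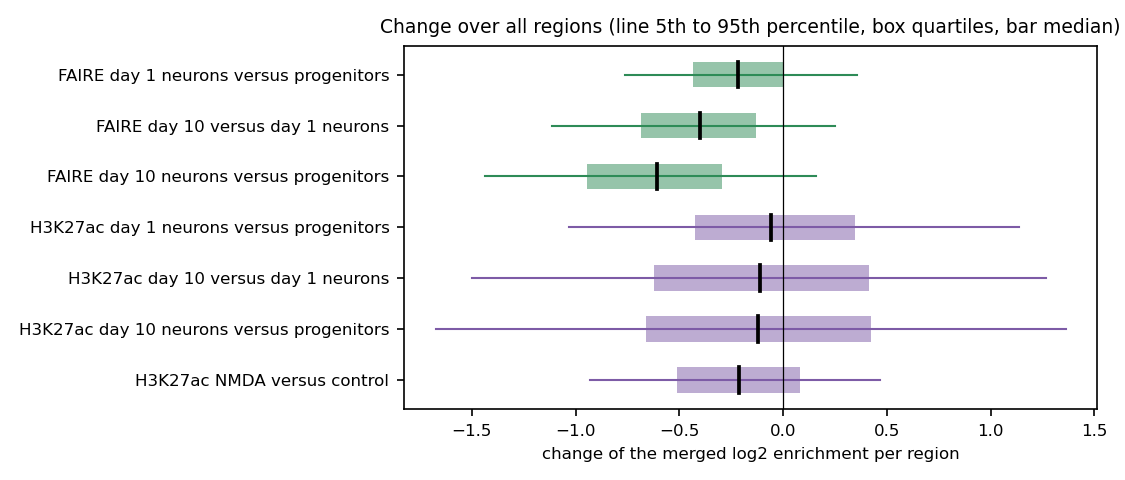
Change of the merged log2 enrichment (x axis) over all regions for each comparison; boxes span the quartiles, lines the 5th to 95th percentile, and bars mark medians. FAIRE medians lie at -0.22, -0.40 and -0.61, and that of H3K27ac after NMDA at -0.21.

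**Figure D4:**
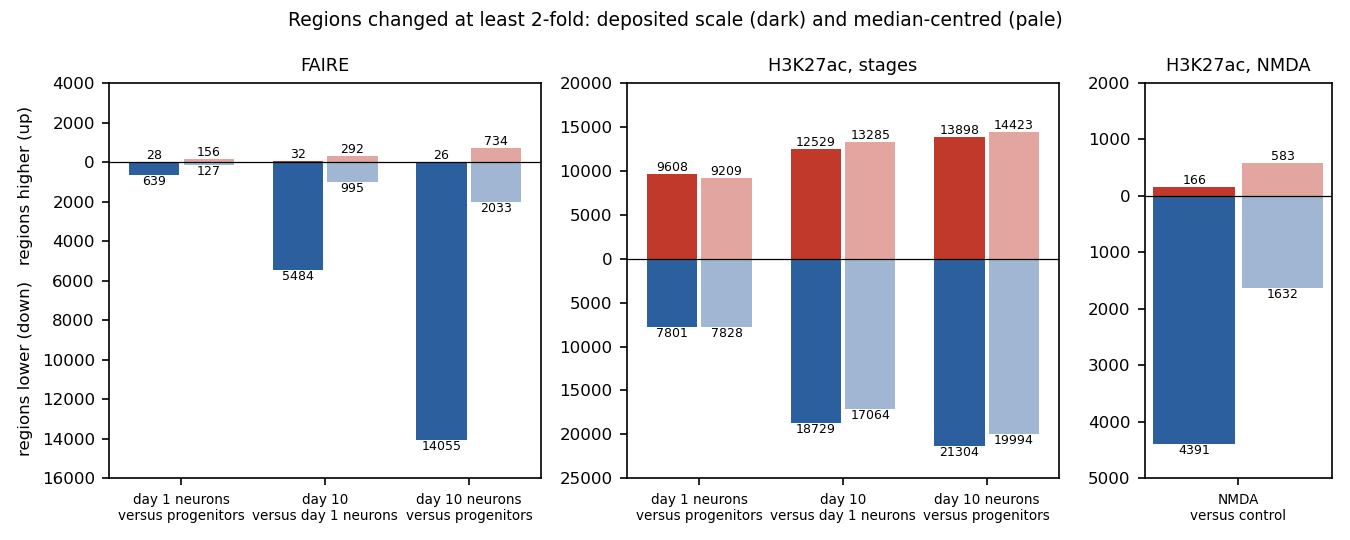
Number of regions higher (up, red) and lower (down, blue) by at least 2-fold in each comparison, dark on the deposited scale and pale after median-centring. FAIRE falls from progenitors to day 10 go from 14055 to 2033, while the H3K27ac falls go from 21304 to 19994.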

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

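Among the alternatives, a constant of 4 reads for the chromatin tables was chosen after the data were examined, and the others before. For RNA, counts stayed within 1.5 times 2845 rises and 2979 falls under other pseudocounts, filters, quantile normalisation, edgeR (2905 and 2877), DESeq2 (2260 and 2324) and an adjusted p under 0.1 (3488 and 3598). A limit of 2-fold left 495 and 209. Leaving out 1 library gave 1060 to 3031 rises and 910 to 3335 falls; a lone library is then assumed to vary like the other group. Of the tested values of 58 named genes, none reversed; Grin1, Rbfox3, Jun and Col19a1 each lost their call without at least 1 library, Jun also with quantile normalisation. Shared replicate numbers gave 2 pairs, whose deviations correlated at 0.34; the labels do not say that a number marks a shared batch. With the replicate block there were 3685 rises and 3782 falls, and 12 lists up and 9 down. The lists gained were endoderm and epithelium genes, up, and AMPA and kainate receptors, down. The main camera test called 11 lists up and 8 down. With an estimated correlation 0 lists went up and 0 down, with 0 at an unadjusted p under 0.05 and a smallest camera p of 0.124. That smallest p was for growth factor genes, whose estimated correlation of -0.039 lay below the preset 0.01, where camera gave p = 0.0179. With 2 libraries per group this test thus cannot decide whether correlation among genes made the calls. Fry called 0 and 0, with 13 at an unadjusted p under 0.05 and a smallest adjusted p of 0.101. Leaving out 1 library gave 9 to 13 lists up and 6 to 10 down.

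No paired analysis was possible for the chromatin tables because each value is merged over libraries; limma without trend, the block, leaving out libraries, other adjusted p limits, the fit of only the compared stages, the pseudocount, and the overlap and window alternatives were not run. FAIRE rises and falls of at least 2-fold were 58 and 39 (progenitors to day 1), 770 and 579 (day 1 to day 10) and 1058 and 916 (progenitors to day 10) with quantile normalisation. In the same order they were 156 and 127, 292 and 995, and 734 and 2033 when median-centred, and 800 and 6044, 709 and 20101, and 474 and 32541 with a constant of 4 reads. H3K27ac after NMDA had 671 higher and 852 lower regions with quantile normalisation, 583 and 1632 median-centred, and 2574 and 13878 with a constant of 4. With the regions of lowest mean left out, 11 FAIRE regions rose from progenitors to day 10 and 101 H3K27ac regions rose after NMDA, fewer regions being counted. Across stages, H3K27ac counts moved by over 1.5 times with a constant of 4 alone, to 17961 gains and 17576 losses, 22980 and 32196, and 23820 and 35214 in that order. A smaller constant lets regions with few reads pass the limit; depth limits those most, with a median of 10 reads per FAIRE region at day 10.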

Other observations

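All tests of explanations in this part, and the gene families, were chosen after the values were seen. Some gene families moved after NMDA, most of them outside the lists set before the data were examined. Of 75 cytosolic ribosomal protein genes, 70 rose and 0 fell by limma (71 and 0 by DESeq2), with a median log2 change of 0.50 that lay above all of 10000 sets matched on mean level (95% of them between -0.18 and 0.02). Their paralogs and pseudogenes can share reads, and the calls were 5 without control replicate 1 and 27 without control replicate 2, at medians of 0.44 and 0.55. Of 37 collagen genes, 25 rose and 2 fell, Col10a1 and Col19a1, the latter losing its call without either control replicate (median 0.95). As 5 of these collagen genes are also in the fibroblast list, part of this count is that list's again; the other 32 had 20 rises and 2 falls (median 0.90). Of 10 laminin genes 6 rose and 0 fell by limma (6 and 0 by DESeq2; median 0.89). Of 21 genes of Wnt ligands and Frizzled receptors, 14 rose and 0 fell by limma (11 and 0 by DESeq2; median 0.92). Of 47 ubiquitin-specific protease genes, 23 fell and 0 rose by limma (21 and 0 by DESeq2; median -0.26). Without control replicate 1, rises were 6 for the Wnt group, and falls 5 for the proteases; without control replicate 2 these were 9 and 14. All 6 family medians kept their sign under each alternative that was run, quantile normalisation included. Sets matched on mean level, here and for the Zfp genes below, treat genes as independent. They do not measure the spread between libraries of genes that vary together.

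Medians of the neuronal lists other than GABAergic markers were lower and those of progenitor, fibroblast and astrocyte lists higher after NMDA. A lower share of neurons as the whole cause would raise every other cell type alike, if neurons expressed none of the genes of those lists. The 6 lists of other cell types, without genes shared between lists, moved apart. The permutation p was 0.00060 over 80 genes and 0.0033 over the 67 with a mean of at least 50. Medians were 1.08 for fibroblast, 0.91 for progenitor, 0.69 for astrocyte (0.31 without NMDA replicate 2) and 0.50 for oligodendrocyte genes (0.93 without NMDA replicate 1). Endothelial and endoderm genes had 0.52 and 0.82 (-0.11 and 0.35 without NMDA replicate 2). The 16 fibroblast genes rose nearly alike (SD 0.099). Neurons may express some genes of these lists, and the permutation takes genes as independent, so these values do not decide on that cause. The pan-neuronal genes did not all lose RNA alike: their changes ranged from -0.81 to 0.26, with a chi-square per degree of freedom of 8.92 around a common value. As a set, though, 46 channel genes (median -0.38) could not be told apart from the 21 pan-neuronal genes (median -0.25, permutation p = 0.233). A loss of neurons, alone or beside changes within cells, stays open. Gene length was not tested, since lengths of the authors' build were not used here.

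Zinc finger genes named Zfp fell as a family: of 329 tested, 150 fell and 19 rose, 1 of the rises being Zfp36 of the immediate early list (82 and 7 without control replicate 1, 105 and 6 without control replicate 2, 127 and 11 without NMDA replicate 2, and 118 and 9 by DESeq2). A trend with expression level as the cause is argued against by the median log2 change of -0.36, below all of 10000 sets matched on mean level (95% of them between -0.02 and 0.11). Reads moved between paralogs of the family would leave its sum in place. Summed over 353 Zfp genes, not only the 329 tested, the values however changed by -0.40 on the log2 scale. Between replicates this sum differed by 0.04 and 0.06. An effect of NMDA on these genes stays open and was not tested apart from other differences between the groups.

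H3K27ac was lower over most regions after NMDA. A difference in depth between the merged libraries as the whole cause would give the same ratio of reads everywhere. The log2 ratio of NMDA over control reads was -0.52 (bootstrap 95% interval -0.52 to -0.51) at regions enriched 4-fold or more and -0.27 (-0.28 to -0.27) at regions of 1- to 2-fold, which argues against it. At 949 regions below the reference it was 0.22 (0.14 to 0.30). A lower signal over background in the NMDA libraries and a loss of acetylation both predict this order, so they cannot be told apart with 1 merged value per group.

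Among FAIRE regions the 5 largest rises from day 1 to day 10 whose mean was at or above the median had log2 changes of 2.25 to 2.80. In 1 of them, 220 bp wide, reads went from 4302 in progenitors to 1075 at day 1 and 7568 at day 10. Median reads per FAIRE region were 22, 17 and 10 at these stages, so this region was far from typical. Its 1075 reads at day 1 gave a log2 enrichment of only 0.08, so its scaled reference was high too. For some others of the 5 the reads could not be recovered. Without coordinates or values per library, a real change in open chromatin could not be told from an artefact at such regions.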
